A study of Mus musculus with 6 samples.

How the data were processed

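RNA sequencing was described for 6 libraries from wild-type C57BL/6 mouse cells, 3 of mature dendritic cells (maDC) and 3 of dendritic cells recovered after coculture with spleen stroma (diffDC). Per the labels, bone marrow cells spent 6 days with the cytokines IL-4 and GM-CSF, then 24 hours with bacterial lipopolysaccharide (LPS), and were purified with magnetic beads against CD11c, an integrin of dendritic cells, to give maDC. Cells treated this way were then kept on spleen stromal cells for 9 days to give diffDC. Per the labels' protocols, total RNA was extracted with TRIzol, and libraries were made and sequenced on an Illumina HiSeq instrument at the Beijing Genomics Institute.

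The table used here gave 1 pooled read number per gene for each group, not a value for each library. The authors' deposited read numbers were read here to be expected counts, because the values carried decimals: within 0.005, 58.2% of the maDC values and 57.5% of the diffDC values were whole. How shared reads were assigned is not given in the sources used here. Whether each column was a sum or another pool of the 3 libraries is not given in the sources used here, and neither are the aligner, the counter and the statistical test. The submitters' processing notes named the builds GRCm38.p4 and mm10. The deposited table also held a log2 ratio of diffDC over maDC, a p-value and, per the file headers, a q-value after Storey. The deposited direction column and gene annotation were not used for any value.

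The deposited log2 ratio was checked against the read numbers. For the genes with reads in both groups, 14573 in number, the deposited log2 ratio differed from the log2 ratio of reads by a constant library factor of 0.127, within 0.001, except in 1 gene. That gene was Zdhhc21, whose deposited log2 cell held 968000, a damaged value. Of 11309 deposited p-values above 1e-250, 11181 (98.9%) lay within 5% of a normal formula for counting noise on the 2 pooled numbers. The deposited p-values therefore compared the pooled reads and carried no spread between libraries. The table held 15282 genes and 1 emptied line, and 23 gene symbols had been turned into dates. List genes were joined by symbol and, where the symbol was absent, by Entrez identifier through a RefSeq gene reference. Of the Entrez identifiers, 15192 matched that reference, which also gave the positions for the test on neighbouring genes. Coordinates of the named genes were taken by symbol from GENCODE M21 on GRCm38.

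Read numbers summed to 69190437 in maDC and 89836110 in diffDC. They were scaled with TMM factors from edgeR 4.0.16 in R 4.3.3, which gave a log2 library ratio of 0.563, against 0.377 from the totals and 0.127 in the authors' deposited log2 ratios. No test across libraries was possible. A gene was called higher or lower when its scaled ratio was at least 2-fold and its exact Clopper-Pearson 95% interval excluded no difference. These intervals cover counting error only, and PCR copies, the assignment of shared reads and differences between cultures are outside them. A value of 0.5 replaced 0 for calls, counts by fold size, list medians and plots. A gene at 0 in 1 group also received a lower bound on its fold, against a floor of 3 reads over the group. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used for the rest.

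The comparison, its normalization, the 24 gene lists and the rule for naming genes were fixed before the data were examined. The calling rule and the random lists were chosen once the table was known to hold pooled values. The lists held 579 entries, of which 548 were measured. The edgeR quasi-likelihood test and the camera list test planned for replicate libraries were not run, because they need values per library. The median log2 ratio of each list was instead placed among the medians of 10000 random lists of the same size matched on mean expression in 20 bins, and called outside when below the 2.5th or above the 97.5th percentile. This describes the pools and is not a test across replicates. The authors' p-values were also adjusted over each list alone. The naming rule took Suclg2 and Lactb from the series title, the 5 largest rises and 5 largest falls among genes with a mean of at least 5 CPM, reads relative to the library total, and for each list the 2 largest changes and the largest change the other way. Predicted genes without a proper symbol were passed over. The planned adjusted p was replaced by the size and counting rule, and the planned lack of overlap between libraries could not be applied. The rule took 65 genes. Further genes given as examples of a list are members of lists fixed beforehand, chosen after their values were seen.

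The procedure was tested on simulated data drawn for the diffDC against maDC comparison over 15282 genes with counting noise only. Of 100 simulated 4-fold genes, 100 were called, and of 100 simulated 2-fold genes, which lie on the size limit, 63 were called. Of 14628 unchanged genes with reads, 52 were called. As many simulated genes were raised as lowered, and they were few beside the 6766 genes called in the data. The simulation therefore does not bear on the choice of scaling or on spread between libraries. Other scalings, expression filters, fold sizes, intervals and the authors' own calls were tried as alternatives. The comparison left out no gene with reads.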

Results

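The data set compared mouse dendritic cells before and after contact with spleen stroma. Dendritic cells grown from bone marrow and matured with LPS (maDC) were set against cells derived from them by 9 days on spleen stromal cells (diffDC), which the series title calls regulatory and tolerogenic. Each group had 3 libraries per the labels, but the values used here were 1 pooled read number per gene and group, 69190437 reads in maDC and 89836110 in diffDC. At least 1 read was listed for 14861 genes in maDC and 14993 in diffDC. No replicate check was possible for any difference, and all intervals are 95% counting intervals on the pooled reads.

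Suclg2 and Lactb, the genes in the series title, changed in opposite directions. Suclg2, the GTP-forming beta subunit of succinyl-CoA synthetase, rose from 219 reads in maDC to 3782 in diffDC, 11.7-fold higher after scaling (interval 10.2 to 13.5). Lactb, a mitochondrial serine protease, fell from 677 to 151 reads, 6.62-fold lower (interval 5.55 to 7.96). The log2 ratios of diffDC over maDC were 3.55 for Suclg2 and -2.73 for Lactb. In the authors' deposited table these log2 ratios were 3.99 and -2.29, since another library factor was used there. Suclg2 (Entrez 20917) spans 95473009 to 95718800 on the minus strand of chromosome 6 in GRCm38, and Lactb (Entrez 80907) spans 66955388 to 66975484 on the minus strand of chromosome 9. Both are annotated as protein coding, and the read numbers are for whole genes. Markers of fibroblasts and reticular stroma rose in the same pool, 22 of 31 genes with a median log2 ratio of 3.91.

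Across the table, 6766 of 15282 genes had a ratio of at least 2-fold whose interval excluded no difference, 3562 higher and 3204 lower in diffDC. The interval of a called gene can still reach under 2-fold. Ratios of at least 10-fold were seen for 1150 genes higher and 1061 lower, and of at least 100-fold for 224 higher and 178 lower. Genes without reads in a group entered these counts with 0.5 reads there, so their lower bounds can fall short of those folds. Ndufa7, with 66.45 reads in maDC and none in diffDC, had a log2 ratio of -7.62 this way, past 100-fold. Its lower bound was 32.7-fold lower. With the authors' library factor, the split of called genes became 4915 higher and 2400 lower. Among the 9957 genes with a mean of at least 5 CPM (reads relative to the library total), the median log2 ratio was 0.06 under the TMM scaling used here. In the authors' deposited table, the median log2 ratio of those genes was 0.49. The authors' deposited table listed 13332 genes with a q-value under 0.05, of which 8892 were higher and 4440 lower in diffDC.

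Among genes with reads in both groups, the largest fall was that of Nos2, the inducible nitric oxide synthase, from 178168 reads to 21 reads, 12535-fold lower (interval 8200 to 20251). Kctd14 fell from 2607 reads to 1 read, 3851-fold lower (interval 691 to 152195). Tex14, Dnah2 and Srms were listed at 0 in diffDC, so their falls have lower bounds alone, at least 1138-fold, 713-fold and 593-fold lower. Their maDC values carried decimals (2311.39, 1447.46 and 1203.6), so shared reads could have been divided. The bounds cover counting error only, and a listed 0 could come from that division. Fat3, an atypical cadherin, had the largest rise among genes with reads in both groups, from 7.09 to 51814 reads, 4946-fold higher (interval 2431 to 12461). Ppp1ca, Hist1h3g, the matrix protein gene Efemp1 and the basement membrane collagen Col4a6 were listed at 0 in maDC, at least 1795-fold, 792-fold, 732-fold and 472-fold higher. Efemp1 and Col4a6 rose in the same pool as the stroma markers, whose median log2 ratio was 3.91. Ppp1ca encodes a phosphatase catalytic subunit used by all cells, so a listed 0 can be a failed estimate. Hist1h3g belongs to a family of near-identical copies whose reads can be divided among them.

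**Figure D1:**
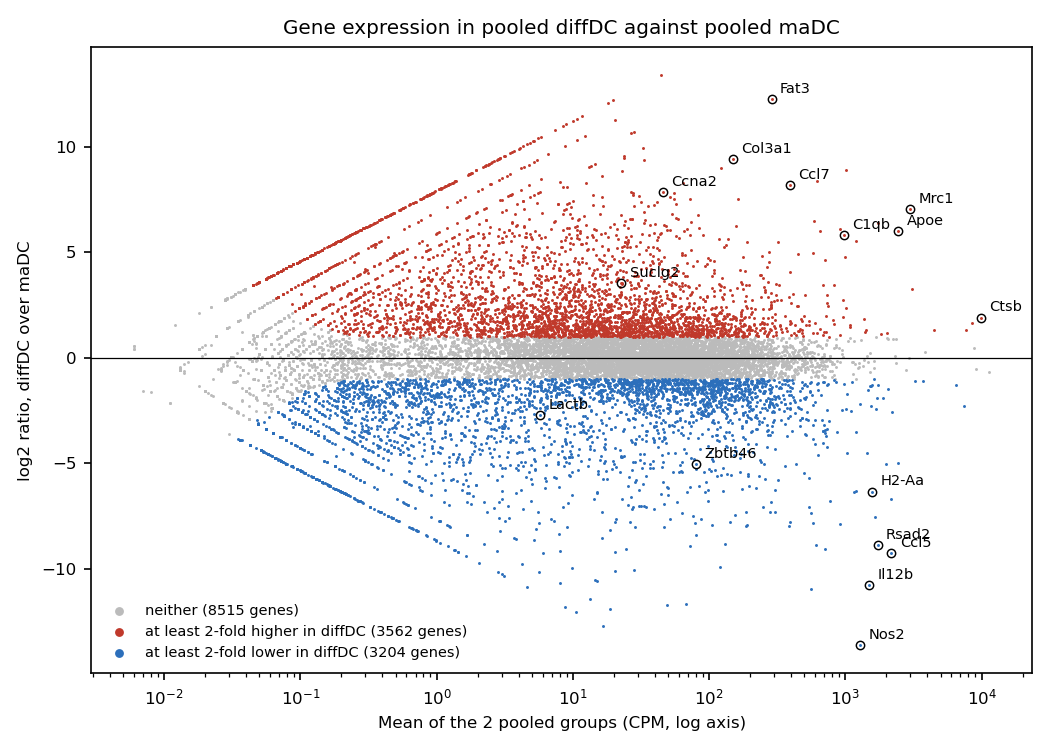
Each point is a gene, with the mean of the pooled groups in CPM on a log axis. The vertical axis is the log2 ratio of diffDC over maDC after TMM scaling. Red and blue points have ratios at least 2-fold higher or lower, with a counting interval that excludes no difference. Genes at 0 in 1 group are drawn with 0.5 in place of 0. Nos2 at -13.61 and Fat3 at 12.27 lie near opposite ends.

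Genes of dendritic cell maturation fell together. Of 27 measured genes of this list, 25 fell and none rose, with a median log2 ratio of -5.05. Il12b, which encodes the p40 subunit of IL-12, fell 1759-fold, from 206009 to 173 reads (interval 1516 to 2054), and Il4i1, an amino acid oxidase, fell 248-fold (interval 212 to 293). Ccr7, the receptor that guides mature dendritic cells to lymph nodes, was 81.9-fold lower, and the costimulatory receptor Cd40 was 42.1-fold lower. Cd86 fell less, by 3.79-fold, while Tnfsf9 and Icosl had log2 ratios of -0.30 and 0.14 and did not pass, and that of Tnfsf9 was 0.14 with the authors' library factor. The list median lay below all of the 10000 matched random lists.

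All 28 measured genes of the type I interferon response fell, with a median log2 ratio of -5.34, below all random lists. Oasl1 was 1968-fold lower (interval 1522 to 2591) and Rsad2, the antiviral enzyme viperin, 470-fold lower (interval 438 to 506). Irf7, a transcription factor that amplifies interferon production, fell 162-fold, and Irf9 fell 3.71-fold. Of 35 inflammatory cytokines and NF-kappaB targets, 25 fell and 4 rose, with a median of -2.43, also below all random lists. The chemokine Ccl5 fell 619-fold, from 301084 to 719 reads (interval 575 to 667), and Il6 fell 81.7-fold. The 4 that rose were all monocyte-attracting or inflammatory chemokines: Ccl7 rose 290-fold (interval 249 to 341), Ccl2 65.2-fold, Ccl4 9.11-fold and Ccl3 3.60-fold. These chemokines rose in the same pool as the stroma markers with a median of 3.91. Tnf had a log2 ratio of 0.35 and did not pass.

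Antigen presentation genes fell in both classes. For MHC class II, which presents peptides to CD4 T cells, 11 of 13 genes fell and 1 rose, with a median of -3.86. H2-Aa was 80.9-fold lower (interval 78.4 to 83.5) and H2-Ab1 80.3-fold lower (interval 77.4 to 83.2), and Ciita, the master regulator of these genes, was 42.1-fold lower. Lgmn, a lysosomal endopeptidase, was the member that rose, 2.97-fold, a log2 ratio of 1.57. For MHC class I presentation, 12 of 16 genes fell and none rose, with a median of -1.92, and Tapbpl and the immunoproteasome subunit Psmb9 were 9.23-fold and 8.46-fold lower. Both medians lay below all random lists. H2 genes are close relatives, so reads could have been divided among them.

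The list of regulatory and tolerogenic molecules went both ways, with 6 of 31 genes higher and 16 lower and a median of -1.09 at percentile 0.09 of the random lists. Entpd1, the ectonucleotidase CD39, rose 7.36-fold (interval 7.11 to 7.62), and Lgals1, encoding galectin-1, rose 6.05-fold, in the same pool as the stroma markers with a median of 3.91. Pdcd1lg2, the checkpoint ligand PD-L2, fell 241-fold (interval 196 to 301), and Cd274, the ligand PD-L1, fell 21.5-fold. Both also belong to the dendritic cell maturation list and were counted there. Il10 and Tgfb1 had log2 ratios of 0.71 and 0.60 and did not pass, but passed at 1.15 and 1.04 with the authors' library factor, which gave 10 genes higher and 14 lower. With genes of at least 5 CPM only, the median of this list was -0.12, within the random lists.

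Markers of conventional dendritic cells mostly fell and macrophage markers mostly rose. Of 20 dendritic cell identity genes, 12 fell and 7 rose, with a median of -1.54 at percentile 0.01, or -2.96 over genes of at least 5 CPM. The lineage transcription factor Zbtb46 fell to a log2 ratio of -5.04 (interval -5.18 to -4.91) and Dpp4 30.0-fold lower, while Wdfy4, needed for cross-presentation, rose to a log2 ratio of 3.46. Clec10a and Cd209a rose further, to 6.89 and 6.76, and Mgl2, Kmo, Sirpa and Cd1d1 rose to 2.36, 1.97, 1.92 and 1.81. Clec10a, Cd209a and Itgae, which fell to -6.03, were under 5 CPM and so outside the median of -2.96. Itgax, which encodes CD11c, had 26978 reads in maDC and 34457 in diffDC, a log2 ratio of -0.21, which turned to 0.23 with the authors' library factor. Of 28 macrophage markers, 20 rose and 4 fell, with a median of 1.87, above all random lists, in the same pool as the rise of stroma markers with a median of 3.91. The mannose receptor Mrc1 rose 134-fold, from 2700 to 535230 reads (interval 129 to 139), the complement gene C1qa 91.4-fold (interval 85.1 to 98.2) and the lipoprotein gene Apoe 64.6-fold. Spic, a transcription factor of iron-recycling macrophages, fell 53.2-fold (interval 41.7 to 68.8).

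Cell cycle genes rose in 28 of 30 cases and none fell, with a median of 2.62 above all random lists. Cyclin A2, Ccna2, rose 231-fold, from 24 to 8177 reads (interval 155 to 360), the kinetochore gene Cenpf 121-fold and Top2a 11.4-fold. The stroma markers with a median of 3.91 rose in the same pool as these and the lysosomal genes. Cenpa and Tyms had log2 ratios of -0.50 and -0.54 and did not pass. Lysosomal genes rose in 14 of 34 cases and fell in 3, with a median of 0.67 at percentile 99.97. Beta-glucuronidase, Gusb, rose 19.7-fold (interval 18.8 to 20.8) and the mannosidase Man2b1 7.80-fold, while the protease Ctsk fell 3.78-fold. Ctsb, another lysosomal protease, held the most reads of any gene in diffDC, 1430990, or 1.59% of the total, and rose 3.77-fold.

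Metabolic lists moved little as groups. The list of succinyl-CoA and succinylation enzymes held 10 genes, among them Lactb, which is a serine protease named in the series title. Suclg2, Oxct1 and Kat2a rose, and Lactb and Hat1 fell, with a list median of 0.35 at percentile 75.6. Sucla2, the ATP-forming beta subunit, and Suclg1, the alpha subunit of succinyl-CoA synthetase, had log2 ratios of 0.38 and 0.58, and Sirt5, the desuccinylase, of 0.12, and these did not pass. Of 23 tricarboxylic acid cycle genes, 4 rose and 1 fell, with a median of 0.37 at percentile 94.6. Isocitrate dehydrogenase 2, Idh2, rose 3.71-fold and pyruvate carboxylase, Pcx, fell 2.21-fold. For oxidative phosphorylation, 3 of 62 genes rose and 2 fell, with a median of 0.08 at percentile 71.5, and examples were Ndufb2 and Atp5g1, 2.37-fold and 2.34-fold higher, and Cox5a, 2.17-fold lower. The second that fell, Ndufa7, was listed at 0 in diffDC. With the authors' library factor, which raised every gene by 0.44 log2, 8 tricarboxylic acid cycle genes were higher and 0 lower, with a median of 0.81, and 10 oxidative phosphorylation genes were higher and 1 lower. Suclg1, Sdhc and Idh3g then passed, at log2 ratios of 1.01, 1.37 and 1.29, and Pcx and Cox5a no longer did, at -0.71 and -0.68.

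Of 19 glycolysis genes, 2 rose and 4 fell, with a median of -0.35 at percentile 25.7. The glucose transporter Slc2a1 fell 4.02-fold, while Pfkm and Aldoc rose 4.67-fold and 4.35-fold. Of 19 genes of mitochondrial fatty acid oxidation, 4 rose and 3 fell, with a median of 0.35 at percentile 84.7, Hadh rising 7.57-fold and Acaa2 7.48-fold and the carnitine carrier Slc25a20 falling 2.90-fold. With the authors' library factor, 9 of these genes were higher and 2 lower. Of 22 cholesterol synthesis genes, 2 rose and 8 fell, with a median of -0.30 at percentile 5.80. Mvd and Idi1 fell 9.39-fold and 8.26-fold, and Dhcr7 rose 5.27-fold. Of 20 immediate-early and heat-shock genes, 6 rose and 3 fell, with a median of -0.14 at percentile 41.9. Egr2 rose 10.8-fold, and the heat-shock genes Hspa1b and Hspa1a, a near-identical pair, fell, with log2 ratios of -4.39 and -3.81. The medians for glycolysis, cholesterol synthesis and stress genes turned positive with the authors' library factor, at 0.08, 0.14 and 0.30.

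Markers of other cell types moved with the same comparison. Of 31 fibroblast and reticular stroma genes, 22 rose and 5 fell, with a median of 3.91, above all random lists. Over genes with a mean of at least 5 CPM the median was 5.66, but that limit favours rises here. Only 5 of the 31 were at 5 CPM or more in maDC, so the others could pass only through diffDC. The fibrillar collagen Col3a1 rose 697-fold, from 26 to 26756 reads (interval 475 to 1066), and the stromal chemokine Cxcl12 205-fold (interval 130 to 346), while the protease inhibitor Timp1 fell 22.5-fold (interval 20.4 to 24.9). With the authors' library factor, 23 rose and 3 fell. Among 16 endothelial genes, 3 rose and 9 fell, with a median of -1.24 at percentile 1.93. Stab1, a scavenger receptor also made by macrophages, rose 24.9-fold, and the receptor Kdr fell 4.37-fold. With genes of at least 5 CPM only, the endothelial median was -1.02, within the random lists.

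Markers of other blood cells went both ways in each list. Of 10 B and plasma cell genes, 1 rose and 4 fell, with a median of -2.32 at percentile 2.14, and Spib fell 9.87-fold. Of 15 T and natural killer cell genes, 3 rose and 7 fell, with a median of -1.77 at percentile 3.39. The IL-7 receptor gene Il7r, which held 32886 of that list's 33490 reads in maDC, fell 4.64-fold. Of 18 granulocyte genes, 6 rose and 8 fell, with a median of -0.24 at percentile 19.0, which was 0.19 with the authors' library factor. The iron-binding protein gene Lcn2 fell 22.7-fold and the myeloperoxidase gene Mpo rose 14.5-fold. Of 11 mast cell and basophil genes, 2 rose and 5 fell, with a median of -0.56 at percentile 25.3. Hdc, which makes histamine, fell 218-fold, from 2809 to 19 reads, and Il1rl1, the IL-33 receptor gene, rose 67.5-fold. With genes of at least 5 CPM only, the mast cell median was -1.80 and lay below the random lists. Of 10 erythroid and platelet genes, 1 rose and 6 fell, with a median of -5.13 below all random lists, or -3.83 with genes listed at 0 placed at their bound, and Itga2b fell 22.4-fold.

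With the authors' library factor, falling genes numbered 23 for dendritic cell maturation, 23 for inflammatory genes, 10 for MHC class II, 10 for MHC class I, 11 for dendritic cell identity, 6 for T and natural killer cells and 3 for glycolysis. The same factor gave 17 lysosomal genes higher and 2 lower, 22 macrophage markers higher and 3 lower, 4 endothelial genes higher and 8 lower, and 3 cholesterol synthesis genes higher and 7 lower. It gave 7 granulocyte genes, 7 stress genes and 4 succinyl-CoA genes higher, and left the calls of the interferon, cell cycle, B cell, mast cell and erythroid lists at the same counts.

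Of the 24 lists, 4 lay above and 10 below the central 95% of the random lists. Falling lists shared genes, among them Il12b, Relb, Ptgs2, Cxcl10, Cd274 and Pdcd1lg2, so their results are not separate. When the authors' p-values were adjusted over the list alone instead of over all genes, the count of members past q 0.05 and 2-fold differed in 3 lists: macrophage markers with 23 against 24, B and plasma cells with 5 against 6, and T and natural killer cells with 9 against 10.

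**Figure D2:**
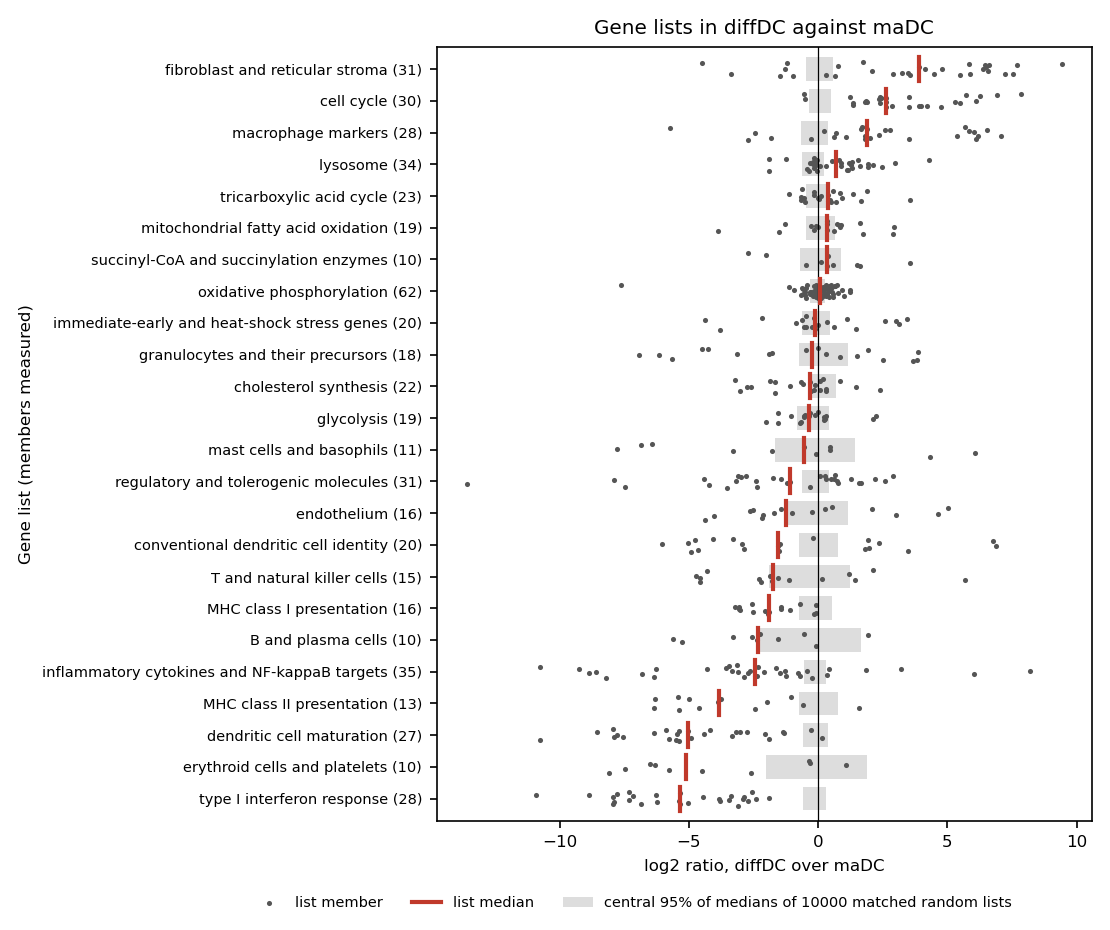
Each gray point is a member of a gene list, placed by its log2 ratio of diffDC over maDC after TMM scaling; red bars are list medians, shaded bars span the central 95% of medians of 10000 matched random lists, the number of measured members follows each name, and genes at 0 in 1 group are drawn with 0.5 in place of 0. Medians run from -5.34 for the type I interferon response to 3.91 for fibroblast and reticular stroma.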

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

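Choices made only after the data were seen were the calling rule itself, the totals, the authors' library factor, the CPM filters, the 4-fold and 99% rules, the authors' own calls, unmatched random lists and lists of genes over 5 CPM; the median-ratio and upper-quartile factors and the removal of stromal and endothelial genes were planned. Of the changed genes, 52.6% were higher in diffDC, against 54.2% with upper-quartile factors, 59.3% with totals, 67.2% with the authors' factor, 56.4% and 55.3% among genes of at least 1 and 5 CPM, and 66.8% and 67.9% by the authors' q under 0.05 and 0.01 with a log2 ratio of at least 1. The factor itself differs by 0.44 log2, which shifts every gene up. The 6766 changed genes became 3750 among genes of at least 5 CPM and 3829 at 4-fold, since both conditions are narrower. Suclg2 was 3.99 and Lactb -2.29 with the authors' factor. The genes taken by the naming rule moved by more than any scaling shift, and a scaling moves random lists alike, so neither bears on stability. Smaller ratios can turn, as 4 list medians did. The 14 lists outside the random range were 12 of 22 without stromal and endothelial genes, 15 with unmatched lists (T and natural killer cells then below) and 11 of 21 over 5 CPM, of which 10 were among the 14.

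No paired analysis was possible because the table gives 1 value per group. For the same reason the DESeq2 and edgeR tests, the test against 2-fold, leaving out libraries, the estimated list correlation and filters counted over libraries were not run. The planned settings for normalized values did not apply. Few members reached 5 CPM in the endothelial (3 of 16), mast cell (3 of 11), T and natural killer cell (1 of 15), B cell (0 of 10) and erythroid (0 of 10) lists.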

Other observations

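The gene families, and all tests below except that on neighbouring genes, were chosen only after the data were seen. Among genes with a mean of at least 5 CPM, 55 of 57 replication-dependent histone genes were higher in diffDC and none lower, with a median log2 ratio of 3.51; near-identical copies can share reads. Of 17 collagens, 15 were higher and 1 lower, with a median of 6.63, but 9 of them belong to the stroma list and largely repeat its result. Of 7 Cd300 receptors of myeloid cells, 6 were higher, with a median of 4.59, and Cd300ld rose from 432 to 16947 reads. Of 9 Toll-like receptors, 6 were higher and 1 lower, with a median of 1.63; Tlr8 rose from 535 to 16140 reads and Tlr9 fell from 2273 to 741. Of 8 guanylate-binding proteins induced by interferon, 6 were lower and none higher, with a median of -4.90, and Gbp2 fell from 73034 to 2076 reads.

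Membrane transporters and chemokine receptors moved as well. Of 29 ATP-binding cassette transporters, 16 were higher and 2 lower, with a median of 1.09, and Abcc3 rose from 285 to 21041 reads. Chemokine receptors divided, with 4 of 9 higher and 4 lower, Ccr7 and Cx3cr1 being members of fixed lists: Ccr2 and Cx3cr1 rose from 44 to 3660 and from 42 to 4509 reads, while Ccr4 fell from 1845 reads to 1 read. Of 6 TGF-beta ligands, receptors and induced genes, 4 were higher and 1 lower, with a median of 2.22, Tgfb1 and Tgfbi being in the regulatory list, and Tgfbr2 rose from 1792 to 40942 reads, in the same pool as the stroma markers with a median of 3.91. With the authors' library factor, 5 TGF-beta genes, 5 chemokine receptors and 18 transporters were higher. Ribosomal protein genes moved little: of 74 cytosolic members 4 were higher and 2 lower, and of 76 mitochondrial members 6 were higher and 4 lower, with medians of -0.24 and 0.19. The cytosolic median flipped to 0.20 with the authors' library factor, which left 7 members higher and 0 lower and gave 16 higher and 0 lower mitochondrial members.

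Scaling is argued against as the whole cause of the rise of stroma genes in diffDC, because it moves all genes alike, while the list median lay at percentile 100 of the matched random lists, whose upper limit was 0.58. RNA of spleen stromal cells carried into the diffDC pool may account for it and cannot be told apart from expression of matrix genes by the diffDC themselves, because 0 libraries of spleen stroma alone were analysed. Of the 31 genes, 5 were at 5 CPM or more in maDC and 0 were in another list, and the labels name a CD11c selection before the coculture but none after it. Col3a1, Dcn and Col6a1 reached 26756, 13143 and 13054 reads, at log2 ratios of 9.44, 6.45 and 7.55. Fn1 reached 137671 of the list's 285311 diffDC reads, but at a smaller log2 ratio of 3.46. Thy1, Tagln and Timp1 fell, as did Igfbp7 and Fstl1, which no longer passed 2-fold with the authors' library factor. Whether stromal cells also contributed to the higher cell cycle genes, histones and Suclg2 in that pool stays open and was not tested.

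The fall of interferon and maturation genes was weighed next. Unchanged maDC making up at least 10% of the diffDC pool would leave each gene at 10% of its maDC level or more, but for 20 of 28 interferon genes (71.4%) the counting interval lay under that level, and for 18 under the scaling that gave the fewest. The tables do not exclude that most maDC were replaced by other cells, such as macrophages that came through the CD11c selection or other cells of the coculture; Itgax, which encodes CD11c, had a log2 ratio of -0.21, or 0.23 with the authors' library factor. Time since LPS and the coculture cannot be told apart, because 0 maDC libraries were kept for the coculture days without stroma. A change of the cells on stroma, which the design names, therefore stays open beside both.

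Listed zeros in diffDC were weighed last. There were 45 genes with at least 50 reads in maDC and none in diffDC, among them Tex14, Dnah2 and Srms. If reads of a more abundant gene within 5 kb had produced the maDC values, such neighbours would be common. Of the 45 genes, 6 (13.3%) had a neighbour with at least 10 times the reads. Random sets matched on maDC reads had a median of 31.1%, and their central 95% reached up to 44.5%. Those sets held only genes with reads in diffDC, where reads of a neighbour would be listed too. The lower share can follow from that selection, so it cannot decide the question. Ndufa7, a respiratory chain subunit beside the ribosomal gene Rps28, was 1 of those 6. Rps28 had 16755 reads in maDC and 27214 in diffDC, and the 6 neighbours had log2 ratios from -1.23 to 1.05. A steady share of such a neighbour's reads would have left reads in diffDC, where 0 was listed. These values argue against the explanation for the 6 genes. No biological explanation was tested.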
